A study of Mus musculus with 2 samples.

How the data were processed

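RNA was measured by sequencing in 2 libraries of mouse kidney macrophages, 1 sorted as CD11c-positive (R2a) and 1 as CD11c-negative (R2b). Per the labels, kidneys of C57BL/6 mice aged 8 weeks were perfused and digested with collagenase and DNase, the cells were stained and sorted by flow cytometry, and the RNA of 6 to 8 mice was pooled before sequencing. Each population therefore had 1 library, the spread between animals was not measured, and no p-value across genes is given. The libraries were made with a ribosomal RNA reduction step and read as paired ends of 75 bases, per the labels' protocols.

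The deposited values were whole-number counts of reads per gene. Per the labels' protocols and the submitters' processing notes, the authors made base calls with bcl2fastq 2.18.0.12, aligned the reads with STAR 2.5.3 to the mouse build GRCm38 and counted them per gene with HTSeq 0.9.1. The same notes name DESeq2 for differential expression, and its output was not used here. The annotation release, the strand setting and the count mode are not given in the sources used here. Reads of a gene and of an overlapping gene on the other strand therefore cannot be told apart with certainty. Reads with several alignments were left out of the gene counts by the counter, so genes with near-identical copies have incomplete counts.

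The table held 48795 rows naming a gene and 5 summary rows of the counter. The summary rows stayed out of library sizes and of every comparison. Reads assigned to genes made up 47.9% of all rows in R2a and 50.3% in R2b. Gene symbols and positions came from an annotation of GRCm38. Of the gene identifiers, 41341 matched it with their version and 48349 matched without the version, and 446 had no match and kept their identifier. No read in either library was assigned to 24180 genes.

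Counts were scaled with the TMM method of edgeR 4.0.16 in R 4.3.3 and expressed as CPM, the count of a gene relative to the scaled library total. The log2 ratio of a gene was taken as log2 of CPM plus 0.5 in R2a over CPM plus 0.5 in R2b, so it understates the difference of genes with few reads. Folds were ratios of CPM without the added 0.5. Each fold has an exact 95% interval (Clopper-Pearson, on the split of the gene's reads between the libraries, scipy 1.17.1). A gene was called higher or lower in R2a when its log2 ratio was at least 1 in size, its CPM was at least 1 in the higher library and the interval excluded a ratio of 1. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only, and the calls compare these libraries and not the populations. A fold against a count of 0 was computed against a floor of 3 counts, which is 0.254 CPM of the total of R2a and 0.125 CPM of the total of R2b before scaling.

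Before the data were examined, 40 gene lists with 757 genes were written down, and the main settings, the alternatives and the rule for naming genes were fixed. For each list with at least 3 members over 1 CPM, the median log2 ratio was set against the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these 2 libraries only. The genes named were the 12 sort and identity genes, the 12 highest and 12 lowest ratios among called genes with at least 10 CPM, up to 4 members of each list with the largest ratios among those with at least 5 CPM, and the 5 genes with the most reads in each library. Unnamed gene models, immunoglobulin and T cell receptor segments, histone, mitochondrial, small RNA and sex-linked genes were left out of the ranking by ratio. Other called members of a list are named where a count was small, and these were chosen after their values were seen. Several of them, named without a fold, were under 5 CPM in both libraries. The results of some genes that the rule names are not reported here.

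The calls were tested on simulated data for R2a against R2b, with counts drawn for 24030 genes from the real means and library sizes and 200 genes changed. Of 50 genes set 3-fold higher 49 were called, and of 50 set 3-fold lower 46 were called. All 50 genes in each direction were called at 6-fold. Among 15256 unchanged genes over the CPM minimum 8 were called. Of 200 random lists 10 had a median outside the central 95% of their random range. The simulation held counting error only. Changes were placed only in genes with mean expression above the CPM minimum of the calls, so recovery of genes near that minimum was not measured.

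Alternatives were total-count, upper-quartile and DESeq2 1.42.0 scaling, a library size without technical gene classes, added values of 0.1 and 2 CPM, no CPM minimum and a minimum of 5, R2b thinned at random to the total of R2a, 4-fold and 1.5-fold size rules, random lists not matched on expression, and lists without members that another list holds. Restrictions to protein-coding genes, to genes sharing no sequence with ribosomal or mitochondrial transcripts and to lists without immediate-early genes were added after the data were seen. Tables were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.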

Results

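Gene expression was compared between CD11c-positive (R2a) and CD11c-negative (R2b) resident macrophages from the kidneys of adult wild-type mice. The series concerns resident macrophages in renal cystic disease, and the comparison addresses how these populations of the healthy kidney differ in expression. Each population was represented by 1 library of RNA pooled from 6 to 8 mice, so no difference has a replicate check. The R2a library held 11811923 reads on genes and the R2b library 23915896, which is 2.02 times as many. Reads were found on 22763 genes in R2a and on 22581 in R2b. Intervals in parentheses are exact 95% intervals of the counting error.

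The R2a library held more RNA of the chemokine receptor Ccr2 and of the macrophage elastase Mmp12 than the R2b library. It held less RNA of the scavenger receptor Cd163, the coagulation factor subunit F13a1 and a set of genes of alternatively activated macrophages. RNA of pooled sorted cells does not tell different expression within a cell type from a different mix of cells, and neither was tested for these genes. The transcript of the sort marker CD11c, Itgax (ENSMUSG00000030789.9, GRCm38 chromosome 7, 128129547 to 128150657), checked the labels. It stood at 367 CPM in R2a and 48.9 CPM in R2b, 7.49-fold higher (7.02 to 8.00), and is not a finding because the cells were sorted on its protein. Ccr2 (ENSMUSG00000049103.13, chromosome 9, 124101950 to 124113557), the receptor that draws monocytes out of the bone marrow, stood at 267 CPM in R2a and 29.7 CPM in R2b, 8.98-fold higher (8.27 to 9.76).

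The other identity genes did not reach the 2-fold rule. The mannose receptor Mrc1 came closest, at 858 CPM in R2a and 1651 CPM in R2b, with a log2 ratio of -0.94. The log2 ratio was -0.42 for Csf1r, the receptor for the macrophage growth factor CSF1, and -0.39 for the integrin Itgam. It was -0.23 for Adgre1, which encodes F4/80, -0.21 for the fractalkine receptor Cx3cr1 and 0.38 for the pan-leukocyte gene Ptprc. The class II gene H2-Ab1 had a log2 ratio of -0.14, the Fc receptor Fcgr1 -0.08 and the lysosomal glycoprotein gene Cd68 -0.02. Under total-count scaling, which shifts ratios up by about 0.08, the last pair lie at or above 0. Ly6c2, a marker of inflammatory monocytes, had 5 reads in R2a and 0 in R2b and was not over 1 CPM in either library.

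Of 15603 genes over the CPM minimum, 301 were higher and 287 were lower in R2a, and 96.2% did not pass the rule. At least 4-fold differences were found in 41 genes higher and 16 lower in R2a. The median log2 ratio of all genes compared was -0.01, with quartiles at -0.20 and 0.19. Among 12664 protein-coding genes, 168 were higher and 206 lower, so other gene classes were more frequent among the higher than among the lower calls. With total-count scaling 377 genes were higher and 240 lower, and the share of higher genes among the calls went from 51.2% to 61.1%. Across genes, which are not independent replicates, log2 CPM of the libraries had a Pearson r of 0.981.

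**Figure D1:**
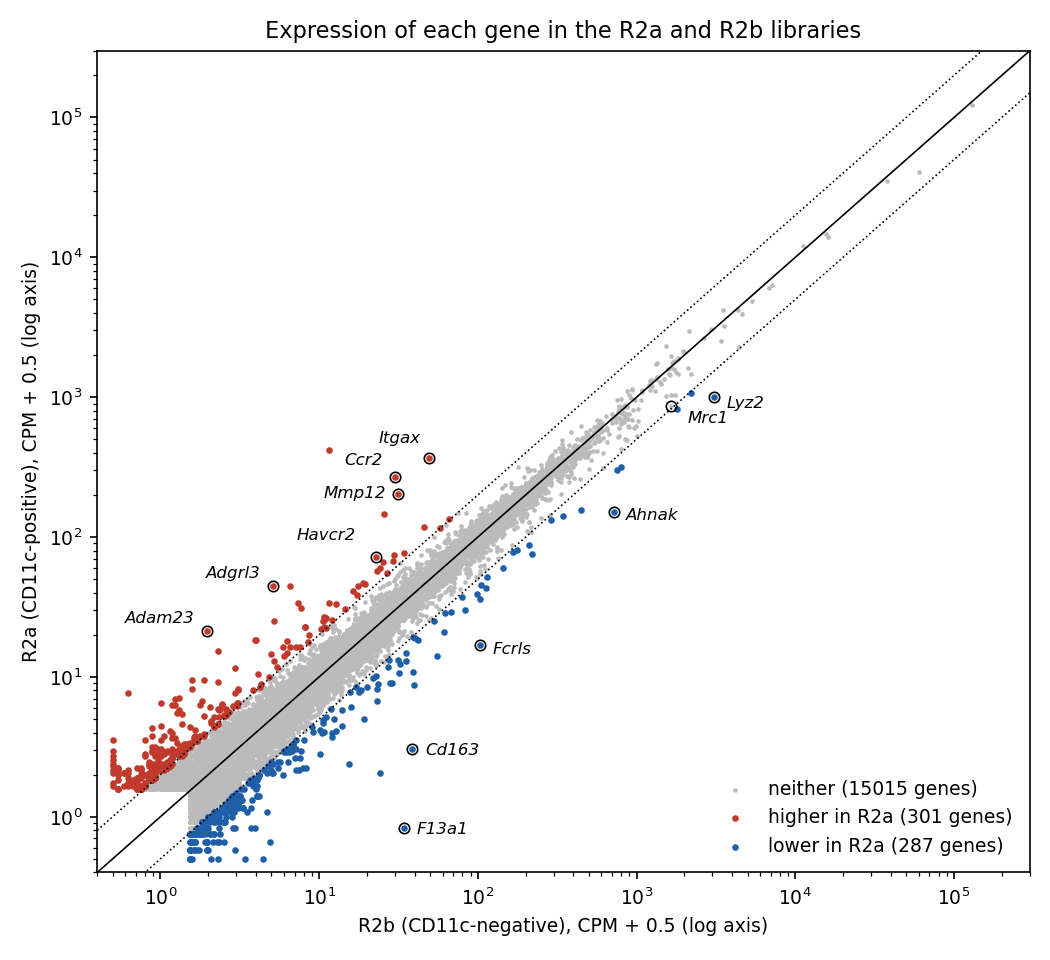
Each point is a gene, with its CPM plus 0.5 in R2b on the x axis and in R2a on the y axis, both on log axes. The solid line marks equal values, the dotted lines a 2-fold difference, and circles mark genes named in the text. The 301 genes higher in R2a and the 287 lower lie mostly at low values, and Ccr2, Mmp12, Cd163 and F13a1 stand well away from the line.

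The named gene highest in R2a relative to R2b was Adam23, a disintegrin family member, at 20.7 CPM against 1.46 CPM, 14.2-fold higher (9.87 to 20.9). The adhesion G protein-coupled receptor Adgrl3 was 9.62-fold higher and Il2ra, the alpha chain of the interleukin-2 receptor, 8.17-fold higher (5.81 to 11.7). Mmp12 stood at 203 CPM in R2a and 31.1 CPM in R2b, 6.54-fold higher (6.02 to 7.11). The mitochondrial leucyl-tRNA synthetase gene Lars2 was 5.77-fold higher (5.25 to 6.35). The SLAM family receptor Cd244a was 5.22-fold higher, the adaptor Grap2 4.27-fold and the checkpoint receptor Havcr2, or TIM-3, 3.19-fold. Sirpb1a was 4.84-fold higher, but has close paralogs among which reads can be split.

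At the other end, F13a1 (ENSMUSG00000039109.15, chromosome 13, 36867178 to 37050244) had 4 reads in R2a and 787 in R2b, 103 times lower in R2a (39.9 to 378). Cd163 (chromosome 6, 124304656 to 124330527), the receptor for haemoglobin-haptoglobin complexes, was 15.0 times lower (10.5 to 22.1). Alox5, a lipoxygenase of leukotriene synthesis, was 15.2 times lower (9.66 to 25.5), with 19 reads in R2a. The betaine and GABA transporter Slc6a12 was 7.82 times lower and the Fc receptor-like scavenger gene Fcrls 6.30 times lower. Ahnak, a giant scaffold protein gene, was the most abundant of these, at 151 CPM in R2a and 716 CPM in R2b, 4.75 times lower (4.52 to 4.98). The chemokine receptor Ccr1 was 4.77 times lower, the imprinted gene Peg10 4.14 times and the chemokine Pf4 3.74 times. Tnfsf9, a costimulatory ligand of the TNF family, was 3.67 times lower, Ms4a4a 3.60 times and the lectin Clec10a 3.33 times, where Clec10a shares sequence with a paralog.

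Genes of alternative activation and scavenging were lower in R2a as a group. Of 15 measured members 9 were lower and 0 higher, and the median log2 ratio of -1.20 lay at percentile 0 of the random lists. Besides F13a1, Cd163, Pf4 and Clec10a, the lower members were Cbr2, Timd4, Igf1, Stab1 and Cd209f, the first a carbonyl reductase. The scavenger receptor Stab1 stood at 824 CPM in R2a and 1809 CPM in R2b. Cd209f had 0 reads in R2a and 24 in R2b, and Timd4, a phosphatidylserine receptor, had 3 and 37, a ratio of 0.155 (0.0307 to 0.491). The 24 resident macrophage genes had a median of -0.13 at percentile 0.97, with 2 members lower. These were lysozyme, Lyz2, at 995 CPM against 3095 CPM, and the lipid receptor Trem2, 2.91 times lower. Apoe had a log2 ratio of -0.96. Leaving out members that another list holds turned the median of the resident macrophage list to 0.03. Genes shared with microglia had a median of -0.13 at percentile 2.33, with Fcrls and Siglech lower, and P2ry12 and P2ry13 at log2 ratios of -0.76 and -0.78.

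Monocyte genes had a median log2 ratio of 0.26 at percentile 99.9. Of 20 measured members 4 were higher in R2a and 1, F13a1, was lower. The higher members were Ccr2, Treml4, Ear2 and Adgre4, of which Treml4 was 6.53-fold higher and Ear2 6.46-fold higher (3.82 to 11.4). The median of the dendritic cell genes lay inside the random range, at 0.05 and percentile 80.5. Of 24 measured members 4 were higher and 1 lower, where 301 of all 15603 genes compared were higher. The peptidase Dpp4 was 2.63-fold higher (2.36 to 2.94) and the chemokine receptor Xcr1 of cross-presenting dendritic cells 2.58-fold higher (1.76 to 3.82). Clec9a, another marker of those cells, had a log2 ratio of 0.83. The chemokine Ccl22 had 25 reads in R2a and 0 in R2b, and the cytokine subunit Il12b had 26 and 16. Siglech, a marker of plasmacytoid dendritic cells and microglia, was 2.88 times lower.

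Chemokine receptors and adhesion genes went both ways, with 4 of 22 higher, 1 lower and a median of 0.06 at percentile 90.6. Beside Ccr2 and Itgax the higher members were the integrin chain Itgb7, 2.14-fold (1.81 to 2.54), and the receptor Cxcr3, and the lower member was Ccr1. Of 18 measured chemokines 4 were lower and 3 higher, with a median of -0.26 at percentile 0.02. The neutrophil attractants Cxcl1 and Cxcl2 were 3.39 and 2.63 times lower, and the monocyte attractant Ccl7 was 4.30 times lower. Ccl22, Cxcl9 and Ccl5 were higher. Inflammatory cytokine genes had a median of -0.45 at percentile 0, with 3 of 18 lower and 2 higher. The cytokine signalling inhibitor Socs3 was 2.88 times lower, the cytokine Osm 2.34 times and the prostaglandin synthase Ptgs2 2.18 times, whereas Il1a was 2.83-fold higher (1.90 to 4.25). Among 25 growth factor genes 3 were lower, Bmp2, Osm and Igf1, with a median of -0.21 at percentile 0.19.

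Genes induced by tissue dissociation lay below the random range in the same libraries. Of the 26 members 22 had ratios below 0 and 4 passed the rule, with a median of -0.65 at percentile 0. The 7 heat-shock members alone had a median of -0.11. The lower members were Fosl2, 2.92 times, Fosb, 2.52 times, Egr2, 2.46 times, and Fos, 2.03 times, all immediate-early transcription factors. Fos did not pass the rule under total-count scaling. Macrophage transcription factors had a median of -0.19 at percentile 0, with Klf4, Klf2 and Bhlhe41 lower and Runx2, a factor of osteoblast development, 2.76-fold higher (2.07 to 3.69). Bhlhe41, 2.07 times lower (1.64 to 2.64), lay at the edge of the rule and did not pass it under 3 other scalings. Complement genes had a median of -0.39 at percentile 0.01. The lower members were C4b, 2.35 times and with a close paralog, and Serping1, and the only higher member of 17 was the sort marker Itgax.

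Class II presentation genes lay below the random range with a median of -0.16 at percentile 1.11, although 0 of 18 passed the rule. The largest ratios were -0.73 for the costimulatory ligand Cd80, -0.62 for H2-DMb2, -0.55 for Cd83 and -0.46 for H2-DMa. Class I genes had a median of 0.01 at percentile 68.2 and 0 of 14 passed. Interferon response genes were shifted up together, with 24 of 30 above 0 and a median of 0.23 at percentile 100, but only Ifi44 passed the rule, 2.40-fold higher (1.93 to 2.98). The antiviral synthetases Oas3 and Oas2 had log2 ratios of 0.77 and 0.69 and the GTPase Gbp3 0.65.

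Of the kidney cell types, proximal tubule genes were at similar levels, with 0 of 26 passing and a median of -0.01 at percentile 54.3. Their summed CPM was 5480 in R2a and 5514 in R2b. Distal nephron genes had a median of -0.07 at percentile 17.3 and 1 of 24, Atp6v1g3, was higher, at under 5 CPM in each library. Podocyte genes lay above the random range with a median of 0.55 at percentile 100, although 2 of 10 passed the rule and their summed CPM, which includes 2 genes over 100 CPM, was 820 in R2a and 828 in R2b. The transcription factor Wt1 was 2.85-fold higher (1.91 to 4.30), whereas Podxl and Synpo had log2 ratios of 0.78 and 0.40. Endothelial genes had a median of 0.39 at percentile 100, with Pecam1 at 0.97 and Plvap at -0.83. Cldn5 and Robo4 were higher among 20, and both were under 5 CPM in each library. Fibroblast and pericyte genes had a median of -0.41 at percentile 0.28. The collagens Col1a2 and Col3a1 were 2.21 and 2.61 times lower, and Dcn, under 5 CPM in each library, was lower.

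Many markers of other blood cells were not over the CPM minimum in either library. The summed CPM in R2a and R2b was 232 and 239 for B and plasma cell genes and 142 and 171 for T and NK cell genes. It was 79.1 and 87.8 for neutrophil genes and 12.4 and 10.8 for erythroid genes. Only 4 of 17 neutrophil genes were measured, with a median of -0.47 at percentile 1.39. It was -0.28 at percentile 9.54 with technical gene classes left out of the library size, inside the random range, and Mmp9 had 2 reads in R2a and 103 in R2b, a ratio of 0.0372 (0.00445 to 0.138). B and plasma cell genes had a median of -0.35 at percentile 1.03. Pax5, under 5 CPM in each library, was lower, and Jchain, Igkc and Cd22 had log2 ratios of -0.95, -0.75 and -0.49. T and NK cell genes had a median of -0.20 at percentile 24.3, with Cd3e lower and Ccl5 higher, both under 5 CPM in each library. The 3 measured erythroid genes had a median of 0.63 at percentile 98.0, which turned to -0.43 without the CPM minimum, and Hbb-bs was lower. Of 12 mast cell, basophil and eosinophil genes 2 were measured and neither passed.

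The remaining lists did not stand apart from random lists at the main settings. Lysosome and phagocytosis genes had a median of -0.09 at percentile 2.90 with 0 of 29 passing, and Ctsb had a log2 ratio of -0.37 and Lgals3 0.48. Lipid and cholesterol genes had a median of 0.01 with Trem2 and the cholesterol exporter Abca1 lower, the latter 2.47 times (2.38 to 2.56), and Lpl at 0.61. Matrix remodelling genes had a median of 0.01, with Mmp12 and Adam8 higher and Mmp9 and Thbs1 lower. Pattern receptor genes had a median of 0.02, with the flagellin receptor Tlr5 2.43 times lower and Cd14 at -0.76. Costimulation and checkpoint genes had a median of -0.02, with Havcr2 higher and Tnfsf9 lower. Iron and heme genes had a median of -0.07, with Cd163 and Steap4 lower, and Fc receptor genes had -0.12 with 0 of 9 passing. The cell cycle list had a median of 0.16 at percentile 96.7 with Ccna2 and Birc5 higher, at 23 and 15 reads in R2a, and Mki67 at a log2 ratio of 0.39. Medians were 0.01 for oxidative phosphorylation, -0.07 for glycolysis and hypoxia, -0.07 for cilium and polycystin genes and -0.06 for ribosomal proteins, with 0 members passing in each. Mitochondrially encoded genes had a median of 0.06, with mt-Nd6, the protein-coding gene of the light strand, 2.55-fold higher (2.24 to 2.89). The strand setting of the counting is not given in the sources used here, so that value is uncertain. Sex-linked genes had a median of 0.14 and the sort and identity list had -0.14. The medians of 7 lists, each within 0.08 of 0, changed sign under another scaling, among them proximal tubule, distal nephron and ribosomal proteins.

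Of the 39 lists with a median, 18 lay outside the central 95% of their random lists, 5 above and 13 below, where chance alone gives 1.95. Of these 18 lists 11 lay outside under every alternative that gave them a median, and the neutrophil, B and plasma cell, erythroid, class II, resident macrophage, microglia and dissociation lists did not. Genes of a list are not independent, and the lists share members. The genes with the most reads were the same in both libraries: mt-Rnr2, Gm26917, mt-Rnr1, Cd74 and mt-Co1. The class II chaperone gene Cd74 had a log2 ratio of -0.10.

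**Figure D2:**
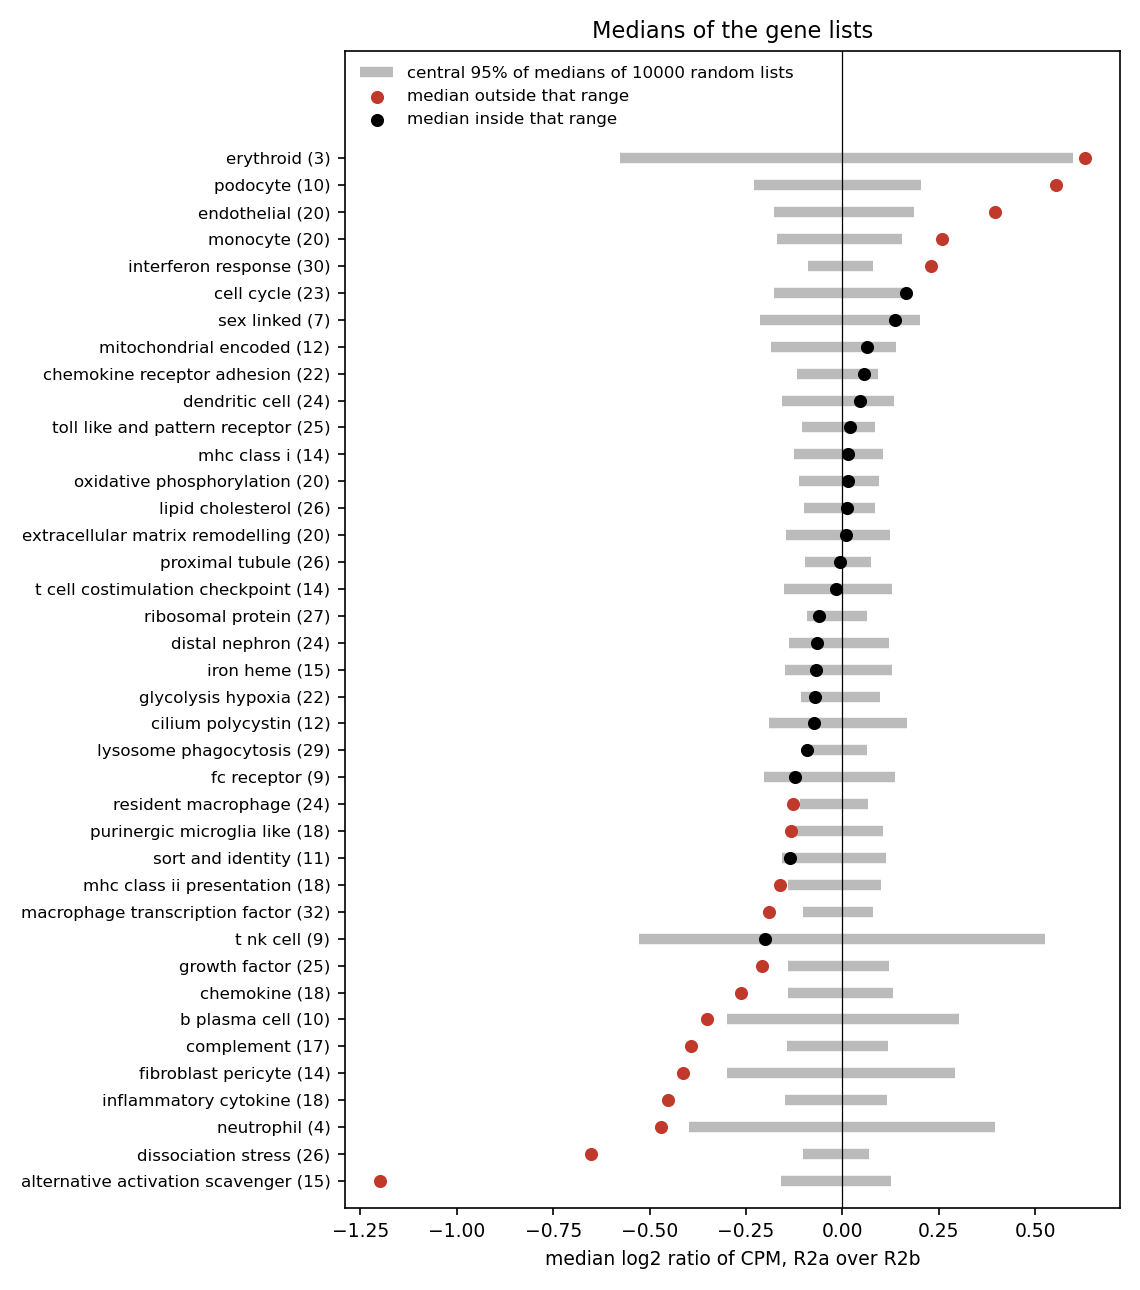
Median log2 ratio of CPM, R2a over R2b, of the 39 gene lists, with the number of measured members in parentheses. Grey bars span the central 95% of the medians of 10000 random lists matched on expression, and red points lie outside their bar. The alternative activation list, at -1.20, lies farthest below and the erythroid list, with 3 genes, farthest above.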

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

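No test of an explanation was run in this part. The groups hold 1 library each, so no library could be compared with others of its group. Reads outside the gene comparisons were the signal found in data not otherwise used, all far above the 3 counts that a count of 0 allows. Reads outside annotated exons made up 41.2% of all rows in R2a and 38.9% in R2b. Reads on several genes made up 2.42% and 2.51%, and reads with several alignments 8.50% and 8.33%.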

How the results depend on the processing

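The restrictions to protein-coding genes, to genes sharing no ribosomal or mitochondrial sequence and to lists without immediate-early genes were chosen after the data were seen. Against 301 genes higher and 287 lower, an added value of 0.1 CPM gave 493 and 462 and one of 2 CPM gave 82 and 78, since the added value pulls ratios of genes with few reads toward 0. A CPM minimum of 5 gave 92 and 97, with fewer genes tested, a 4-fold rule 41 and 16 and a 1.5-fold rule 869 and 903. Protein-coding genes alone gave 168 higher and 206 lower. The other scalings, the thinned library, no CPM minimum and the library size without technical classes gave counts within 1.5 times of the main ones. The number of lists outside their random range was 16 to 18 under all settings run, and 11 lists lay outside under each setting that gave them a median. The neutrophil, B and plasma cell, erythroid, class II, resident macrophage and microglia lists lay inside under at least 1 setting, as did the dissociation list without its immediate-early genes, and the cell cycle, lysosome, chemokine receptor and matrix lists outside. The neutrophil median of -0.47 was -0.28 without technical classes in the library size and -0.21 without the CPM minimum. The erythroid median of 0.63 turned to -0.43 without the CPM minimum, and the resident macrophage median of -0.13 turned to 0.026 without members of other lists. The cause was not tested. Of 59 named genes past the rule, Bhlhe41 lost its call under total-count, DESeq2 and upper-quartile scaling, in the thinned library and with 2 CPM added. Total-count scaling also ended the calls of Col1a2 and Fos, and 2 CPM added those of Col1a2, Col3a1, Il1a, Itgb7, Wt1 and Xcr1. No paired analysis was possible because each population has 1 library. Depth limits R2a more than R2b, with 11811923 against 23915896 reads on genes.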

Other observations

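All tests of explanations in this part, and the gene families, were chosen after the results were seen, so the families are examples picked because members differed. Linker histone genes were lower in R2a, with 4 of 5 measured members called: Hist1h1d was 4.06 times lower (3.44 to 4.80), Hist1h1e 2.91 times, Hist1h1b 2.61 times and Hist1h1c 2.40 times. Adhesion G protein-coupled receptor genes had 4 of 14 higher and 0 lower, with Adgrg5 4.64-fold (3.01 to 7.29) and Adgrg6 2.38-fold higher beside Adgrl3 and Adgre4. Of 9 guanylate-binding protein genes, which are induced by interferon, 3 were higher: Gbp2b 4.84-fold (3.35 to 7.09), Gbp4 2.67-fold and Gbp8 2.60-fold. Of 3 measured Pilr genes, which encode paired receptors of myeloid cells, 2 were higher, Pilra 2.56-fold (2.24 to 2.92) and Pilrb1 2.91-fold, and Pilrb2 had a log2 ratio of 0.96. Of 9 measured Cd300 genes, all with ratios above 0, Cd300lb and Cd300e were higher. Of the Ras activators, Rasgrp1 was higher in R2a, with a log2 ratio of 1.31, and Rasgrp3 2.55 times lower. Paralogs within these families can share reads.

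Outside the mitochondrial genes and the ribosomal repeat model Gm26917, which had a log2 ratio of -0.58, all 10 models over the CPM minimum that share sequence with ribosomal or mitochondrial RNA were called higher in R2a. They ranged from a log2 ratio of 1.53 to 5.18, led by CT010467.1 (chromosome 17, 39846353 to 39848827, minus strand) with 5086 reads in R2a and 257 in R2b. Less complete removal of ribosomal RNA is argued against for the models with most reads, since Gm26917, mt-Rnr1 and mt-Rnr2 together had a fold of 0.869 (0.867 to 0.870). These models do not cover the stretch where CT010467.1 lies. The 9 mitochondrial-like models together carried 110 reads per kilobase in R2a (102 to 118). For 1447 sensory-receptor genes silent in these cells it was 0.0203 (0.0166 to 0.0246). The models had a CPM minimum and the silent genes a CPM maximum, so that gap decides nothing about nuclear DNA. More nuclear DNA in R2a would also raise the silent genes. Their summed fold was 1.09 (0.852 to 1.39), which argues against a rise of nuclear DNA as large as that of the models. A smaller rise, within that interval, is not excluded. Mitochondrial DNA and a difference between the populations were not tested and stay open. So does a difference in strand selection for CT010467.1 and for the light-strand gene mt-Nd6. CT010467.1 lies on the minus strand next to Gm26917, which is on the plus strand and does not overlap it. The sequence that CT010467.1 shares with the plus-strand ribosomal models searched is in the opposite orientation only. The 9 mitochondrial-like models share sequence with mitochondrial transcripts in the same orientation.

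Of 19 immediate-early genes 18 had ratios below 0 and 4 were called lower in R2a, with a median log2 ratio of -0.75. The median was -0.82 with R2b thinned to the total of R2a, below a random range of -0.12 to 0.10, so it did not depend on the difference in depth. Random thinning keeps the expected ratios of abundant genes, so this test could hardly have come out otherwise. A stronger response to handling in R2b may account for it, but the 7 heat-shock genes of the same list had a median of -0.11 within a random range of -0.21 to 0.17, which leaves it open. With 1 sort per population, handling and a difference between the populations cannot be told apart for these genes. The same holds for the genes of cytokines, chemokines and Klf factors that handling can induce.

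The medians of podocyte and endothelial genes lay above their random ranges, at 0.55 and 0.39, although 2 of 10 and 2 of 20 genes were called higher. Of the podocyte genes 2 stand in another list, and the summed CPM of 820 in R2a and 828 in R2b includes 2 genes over 100 CPM, so it says little about the other markers. An even rise of all other cell types in R2a is argued against. The fibroblast and pericyte median was -0.41, below its random range of -0.30 to 0.29, and the proximal tubule and distal nephron medians lay inside theirs. A lower share of macrophages with an uneven mix of other cells is not excluded by these values. Podocytes in the R2a sort are argued against as the source of Wt1, since Nphs1 and Cdkn1c together had a fold of 0.946 (0.708 to 1.26) against 2.85 (1.91 to 4.30) for Wt1. Endothelial cells or fragments in the sort, and a difference between the populations, were not tested.

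The 4 Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y together had 759 reads in R2a and 1032 in R2b, a fold of 1.41 (1.28 to 1.55). Xist stood at 1626 CPM in R2a and 1658 CPM in R2b, so both libraries held RNA of both sexes. The sex of the pooled mice is not given in the sources used here, so the share of male mice in each pool is not known and the fold cannot be read as a difference between the cells. The mitochondrial genes mt-Co2, mt-Co3 and mt-Atp6 had 22, 28 and 14 reads in R2a where mt-Co1 had 170195, and near-identical nuclear copies exist for them, so their counts are incomplete.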
